A study of Homo sapiens with 48 samples.

How the data were processed

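RNA was measured in sorted cells with Affymetrix U133 Plus 2.0 arrays, 1 array per sample. Per the labels, RNA came from PicoPure extractions, was checked for quality on picochips, and was amplified and biotin-labelled with Ovation kits before hybridisation. Each of the 48 columns of the deposited table holds log2 expression per probe set as the authors deposited it, with 0 missing values and a range of 0.688 to 14.8. The method of background correction, summarization and normalization is not given in the sources used here. Array medians differed by at most 0.407, below the limit of 0.5 set for further normalization, so the deposited log2 values were used as they are. Skin replicates 2, 3 and 4 had the highest array means, at 4.315, 4.379 and 4.267, against 4.093 to 4.182 on the other arrays. No scanner files were at hand, so the signal of each probe over its background is unknown.

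The platform annotation paired 41097 of the 54675 probe sets with a single gene, 1801 with several genes and listed no gene for 11777. Only probe sets with a single gene were named, and symbols were looked up in the RefSeq gene table of GRCh38.p14, used for names alone. XIST, TSIX and genes of the Y chromosome were left out, which left 41038 probe sets and 19740 genes. A gene was represented by its probe set with the highest mean over all arrays, which was a choice among several for 10511 genes. Among called genes, 107, 27 and 24 had other probe sets called in the opposite direction in the comparisons with skin, blood and tonsil. No gene was left out for a low level.

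Groups follow the sample titles. Lesion CD207+ samples (n = 13) were compared with skin CD207+ samples (n = 12), the 7 lesion CD3+ samples that share a patient with a blood sample with those 7 blood samples, and all lesion CD3+ samples (n = 12) with tonsil pools (n = 4). Each comparison was a linear model in limma 3.58.1 (lmFit, then eBayes with an intensity trend) under R 4.3.3, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The lesion and blood samples were paired because the series' design text says that they come from the same patients, and the patient was a block in that model. Deviations of same-numbered lesion and blood samples from their group means correlated at -0.184 to 0.301 (median 0.197, with 4 of 7 over 0.1).

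The 3 comparisons, their tests, the rule for named genes, the gene lists and the alternatives, apart from those said to be later, were fixed before the data were examined. Most tests of carried-over RNA, the test between cell types and the comparison of blood with tonsil were chosen after values were seen. The rule for named genes took, for each comparison, the 8 largest increases and the 8 largest decreases among genes past the threshold and above the median level in the higher group. To these it added genes picked in advance and up to 4 members of each list with the smallest p. Immunoglobulin and T cell receptor segments and clone-like symbols were passed over. The 36 lists hold 434 genes, of which 402 were measured and 32 were not analysed here. Lists for CD207+ cells covered Langerhans cell identity, monocyte and macrophage genes, dendritic cell maturation, MHC class II presentation, cytokines and chemokines, chemokine receptors, matrix remodelling and osteoclast genes, Notch pathway, MAPK feedback targets and apoptosis regulators. Lists for CD3+ cells covered the T cell receptor complex and signalling, naive and central memory genes, T cell activation, regulatory T cell genes, inhibitory receptors, cytotoxic effector genes, type 1, type 2, type 17 and follicular helper genes, tissue residence, and chemokines and chemokine receptors of T cells. Cell cycle, interferon response, and immediate early and heat shock genes were used for both. Lists of other cell types covered keratinocytes, melanocytes, T cells, Langerhans and myeloid cells, B cells, plasma cells, fibroblasts, endothelium, eosinophils and granulocytes, mast cells, and erythroid cells and platelets. Several genes stand in more than 1 list.

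Lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with camera's estimated correlation and with fry. Fry asks whether the genes of a list move on balance in a direction and does not compare them with other genes. RNA quality was measured as the mean log2 ratio of 3' over 5' signal of the actin and GAPDH control probe sets and compared by permutation, with 100000 resamples or all arrangements where a group held fewer than 10 samples. The agreement between the comparisons of lesion CD3+ cells with blood and with tonsil was set against 100 simulations of unchanged groups that share the lesion samples. Other splits of the samples were drawn 100 times, or taken as all 64 exchanges within pairs.

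The models were tested on simulated data with 50 genes changed by each of 1, 2, 3 and 4 log2 units among 19740 genes. Against skin 43, 48, 50 and 50 of them were called, against blood 28, 41, 49 and 50, and against tonsil 20, 45, 48 and 50. Of 19520 unchanged genes 9, 7 and 12 were called. Simulated values were drawn independently for each gene, with the same SD in both groups and no patient effect. These counts therefore do not cover correlated genes or groups of unequal spread.

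Alternatives were quantile normalization of the 48 arrays, median centring, leaving out dim genes, the mean of a gene's probe sets, every probe set on its own, eBayes without the trend or with a robust prior, array weights, a fold threshold of 2, RNA quality as a covariate, marker means as covariates, other uses of the replicate numbers, subsets of lesion samples, and leaving out each sample or pair in turn. Chosen after the data were seen, a further alternative left out samples in doubt, and another took the number in the titles as a block between the lesion groups. Samples in doubt were lesion CD3+ samples with CD207 more than 1 log2 unit above the highest blood or tonsil value, and the skin and lesion CD207+ samples with CD207 more than 3 below the group median. Offsets before a logarithm were not run, since the deposited values are already log2. Figures were drawn with matplotlib 3.10.9 from tables made with pandas 2.3.3 and numpy 2.4.6 under Python 3.11.15.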

Results

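Langerhans cell histiocytosis is a disease in which cells bearing the Langerhans cell proteins CD207 (langerin) and CD1A gather in lesions together with T cells and other leukocytes. RNA was measured on 48 arrays of 54675 probe sets each, in cells sorted for CD207 or for CD3, a part of the T cell receptor complex. Lesions gave 13 CD207+ and 12 CD3+ samples, the blood of patients gave 7 CD3+ samples, control skin gave 12 CD207+ samples, and control tonsils gave 4 CD3+ samples, each a pool of 5 tonsils. The values are log2 expression, array medians lay between 3.53 and 3.94, and the number of arrays limits the precision. The median correlation between arrays of a group, taken across probe sets, which are not independent replicates, was 0.976 for tonsil, 0.966 for blood, 0.962 for skin, 0.945 for lesion CD207+ and 0.894 for lesion CD3+ samples. CD207 itself averaged 11.38 ± 1.29 (SD, n = 13) in lesion CD207+ and 11.59 ± 2.15 (SD, n = 12) in skin CD207+ samples. Skin replicate 1 went against its label, with CD207 at 4.77 (others 11.90 to 12.46), CD1A at 5.28 (11.56 to 12.25) and the fibroblast collagen gene COL1A2 at 12.61 (2.41 to 3.36), and was kept in the comparison. In CD3+ samples CD207 averaged 2.31 ± 0.20 (SD, n = 7) in blood, 2.61 ± 0.31 (SD, n = 4) in tonsil and 5.62 ± 3.09 (SD, n = 12) in lesions. There 7 samples lay above 4.00, a limit set 1 log2 unit above the highest blood or tonsil value. Among those below it, lesion replicates 8 and 11 still held CD1A at 4.75 and 5.82, against at most 2.75 in blood and tonsil.

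The first comparison asked how CD207+ cells of lesions differ from the CD207+ Langerhans cells of skin. Lesion CD207+ cells held more SPP1, the gene of the secreted bone and matrix protein osteopontin, at 9.22 ± 1.88 (SD, n = 13) against 4.70 ± 0.92 (SD, n = 12) in skin, a log2 difference of 4.52 (SE 0.56). They held less EPCAM, an epithelial adhesion molecule of Langerhans cells, at 3.35 ± 1.53 (SD, n = 13) against 8.57 ± 1.14 (SD, n = 12), a difference of -5.22 (SE 0.50). Interferon response genes were higher in lesions for 13 of 17 measured members and lower for 0. All 16 measured keratinocyte markers were lower in lesions, with a median difference of -4.92. Every gene group lower in lesion CD207+ cells moved beside them. CD207 (log2 difference -0.20, adjusted p = 0.852) and CD1A (0.36, adjusted p = 0.649) did not pass limma's test, but both values depend on skin replicate 1. Without it CD207 differed by -0.82 (SE 0.35, adjusted p = 0.0907) and CD1A by -0.20 (SE 0.11, adjusted p = 0.195). With lesion replicate 10, where CD207 was 7.26, left out too, CD207 differed by -0.48 (limma adjusted p = 0.00199). Both samples were left out for their low CD207, which narrows its spread. That p-value therefore cannot decide whether CD207 differs. Over all samples CCR6 (0.83) and CCR7 (-0.91), the chemokine receptors of skin-homing and lymph node-homing dendritic cells, did not pass.

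**Figure D1:**
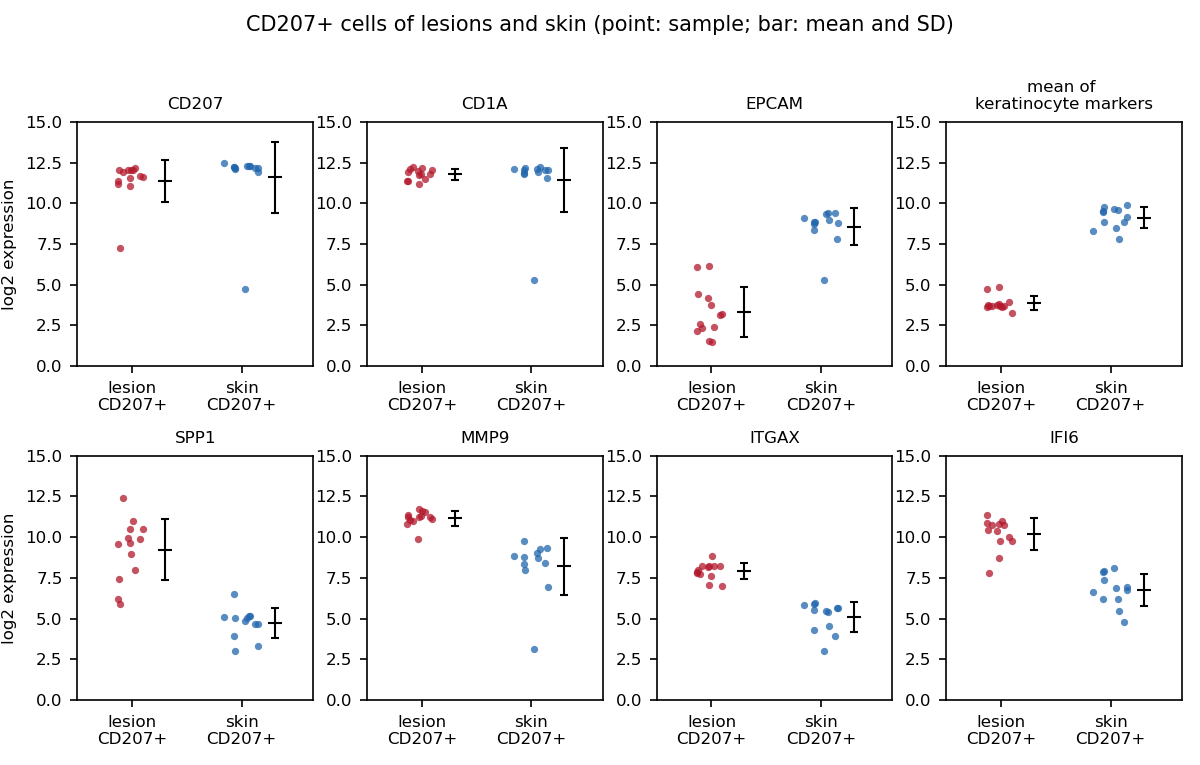
Log2 expression (vertical axis) of 7 genes and of the mean of the keratinocyte markers in lesion and skin CD207+ samples; each point is a sample and the bars give the mean and SD. 1 skin sample is low in CD207 and CD1A, the other 11 average 12.21 and 11.99, EPCAM and the keratinocyte mean lie higher in skin, and SPP1 averages 9.22 in lesions against 4.70 in skin.

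In limma's moderated test with Benjamini-Hochberg adjustment, 4797 of 19740 genes passed, 2104 higher and 2693 lower in lesion CD207+ cells, and 1646 of them differed at least 2-fold (504 higher, 1142 lower). The excess of lower calls was absent after quantile normalization (2742 higher, 2645 lower). Besides SPP1 (adjusted p = 4.72e-07), the genes with the largest increases were ITGA2B, the platelet integrin alpha IIb (4.33), the adaptor SKAP1 (4.30), the myeloid receptor CD300LF (4.25), the galectin LGALS12 (4.17), the scaffold PALS2 (4.11), CNIH3 (4.10) and SFMBT2 (3.98). Those with the largest decreases were KRTDAP (-8.59), SPRR1B (-7.99), KRT1 (-7.98), PERP (-7.86), DSC1 (-7.17), DSC3 (-7.14), CASP14 (-7.05) and CDH1 (-7.01), genes of epidermal differentiation and cell junctions. Of the genes picked in advance, ITGAX, the integrin CD11c, was higher by 2.83, NRP1 by 2.36, AFF3 by 2.40, CD44 by 0.62 and the T and NK cell adhesion gene CD2 by 2.22. The scavenger receptor CD36 was lower (-3.83), while MKI67, a gene of dividing cells (-0.50, adjusted p = 0.328), and TNFRSF11A, the receptor RANK (0.44, adjusted p = 0.22), did not pass.

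Where no count adjusted over the list alone is given beside a list, it equals the count over all genes. Among the fixed gene lists, interferon response genes were led by IFI6 (3.41), HERC5 (1.93), ISG15 (1.82) and MX1 (1.71). The count was 14 adjusted over the list alone, and the list passed camera (adjusted p = 2.46e-07) but not with the correlation among its genes estimated (adjusted p = 0.338 with an estimated correlation). Of the matrix remodelling and osteoclast genes 9 of 19 were higher and 1 lower, with the collagenase MMP1 (2.86), VNN1 (2.94), MMP9 (2.94), MMP12 (2.48) and TIMP1 (1.75) among the higher (camera adjusted p = 0.00217, or adjusted p = 0.145 with an estimated correlation). Cytokines and chemokines were higher for 6 of 20 and lower for 0, including CCL5 (1.82), CCL2 (1.75), TGFB1 (1.36) and CXCL10 (1.32; camera adjusted p = 0.0279; adjusted p = 0.338 with an estimated correlation). Apoptosis regulators were higher for 6 of 15, or 7 adjusted over the list alone, and lower for 0. They included the death-promoting BAX (1.44) and TNFRSF10B (2.23) and the protective BCL2L1 (1.19) and CFLAR (0.98; camera adjusted p = 0.00994; adjusted p = 0.338 with an estimated correlation).

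Other lists of cell state did not pass camera as a whole. Monocyte and macrophage genes were split, 6 higher and 3 lower of 18, with CD14 (log2 difference 2.5) higher and CD36 lower (camera adjusted p = 0.134). Langerhans cell identity genes were lower for 3 of 14, EPCAM, CDH1 and the tight junction gene CLDN1 (-3.16), and higher for 0 (camera adjusted p = 0.123). MAPK feedback targets, a list of genes tied to the growth factor kinase cascade of which some restrain it, were higher for 5 of 16, with DUSP4 (3.39), SPRY4 (2.80) and ETV5 (1.27), and lower for 1, the receptor EPHA4 (-2.23; camera adjusted p = 0.0757). Notch pathway genes went both ways, with the ligand JAG2 (2.19) among 3 higher and NOTCH3 (-3.49), HES1 (-2.81) and JAG1 (-2.09) among 5 lower of 16 (camera adjusted p = 0.308). Chemokine receptors were higher for 3 of 9, led by CCR1 (2.57), and lower for 1, CCR2 (-1.46; camera adjusted p = 0.247). Dendritic cell maturation genes were higher for 1, EBI3 (1.93), and lower for 2 of 14, CCL22 (-3.27) and IDO1 (-1.91; camera adjusted p = 0.999, with a median of -0.10 and a camera direction upward). MHC class II presentation genes were higher for 1 of 11, the protease CTSH (0.83), and lower for 0 (camera adjusted p = 0.436). Cell cycle genes were lower for 3 of 20, TOP2A (-1.31), CDK1 (-1.21) and AURKA (-1.03), or 0 in limma's test adjusted over the list alone, where 6 passed unadjusted (camera adjusted p = 0.0757). Immediate early and heat shock genes, which respond to handling of cells, were lower for 6 of 14, with ATF3 (-2.40), DUSP1 (-0.99) and JUN (-0.91), and higher for 1, HSPH1 (0.91; camera adjusted p = 0.0511).

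Markers of other cell types were measured beside these groups. Keratinocyte markers were lower for 16 of 16, among them DSG1 (-6.55) and KRT10 (-4.23), in camera (adjusted p = 3.51e-35) and with the correlation estimated (adjusted p = 0.000886 with an estimated correlation). Melanocyte markers were lower for 3 of 7, TYRP1 (-4.07), PMEL (-1.24) and MLANA (-1.19), and higher for 1 (camera adjusted p = 0.0735). Plasma cell markers were lower for 2 of 9, including SDC1 (-4.52), which keratinocytes also express (camera adjusted p = 0.417), fibroblast markers for 1 of 11, DCN (-2.32; 0.881), and mast cell markers for 1 of 7, KIT (-1.70; 0.634). B cell markers were higher for 2 of 11, CD79B (0.42) and CD22 (0.37; camera adjusted p = 0.0441; adjusted p = 0.338 with an estimated correlation). Lesion replicate 10 stood apart in the B cell gene MS4A1, at 6.41 against at most 3.175 in the other lesion CD207+ samples. Erythroid and platelet markers were higher for 3 of 8, or 4 adjusted over the list alone, with ITGA2B ahead of HBB (1.26; camera adjusted p = 0.0483; adjusted p = 0.145 with an estimated correlation). T cell markers had 1 higher and 1 lower of 12 (camera adjusted p = 0.0757). Lesion replicate 8 stood apart in CD3D (7.44), CD3E (5.88) and CTLA4 (8.08), and replicate 9 in CTLA4 (6.66), where the other 11 samples reached at most 4.99, 3.13 and 4.20. CD2 and CCL5 kept their calls without replicate 8 (2.17 and 1.55) and without replicate 9 (2.31 and 1.79). Endothelial markers had 1 higher of 10, PECAM1 (1.36; 0.881), and eosinophil and granulocyte markers 1 higher of 11, PRG2 (0.78; 0.303). The log2 ratio of 3' over 5' signal of the actin and GAPDH control probe sets was 1.39 ± 0.21 (SD, n = 13) in lesion and 1.69 ± 0.21 (SD, n = 12) in skin samples. The difference was -0.30 (2-sided permutation p = 0.00127; adjusted p = 0.00381 over 3 comparisons). With that ratio as a covariate 2778 genes passed limma's test. With the mean of the keratinocyte markers as a covariate, which correlated with the group at r = -0.980, 1 gene passed and 2450 had an unadjusted p under 0.05.

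The next comparison asked how CD3+ cells of lesions differ from CD3+ cells in the blood of the same patients, over 7 pairs. Lesion CD3+ cells held more FOXP3, the transcription factor of regulatory T cells, at 7.00 ± 1.12 (SD, n = 7) against 4.71 ± 0.30 (SD, n = 7) in blood, a log2 difference of 2.29 (SE 0.37) that was positive in 7 of 7 pairs. Of 16 measured regulatory T cell genes, 14 were higher and 0 lower, including the inhibitory receptor CTLA4 (2.97, SE 0.25) and the interleukin 2 receptor gene IL2RA (3.34, SE 0.56). Genes of naive and central memory T cells, which circulate between blood and lymph nodes, were lower for 10 of 12 and higher for 0. The same lesion samples held more Langerhans and myeloid cell markers, with 16 of 16 higher and a median difference of 3.04. Every gene group higher in lesion CD3+ cells moved beside them.

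**Figure D2:**
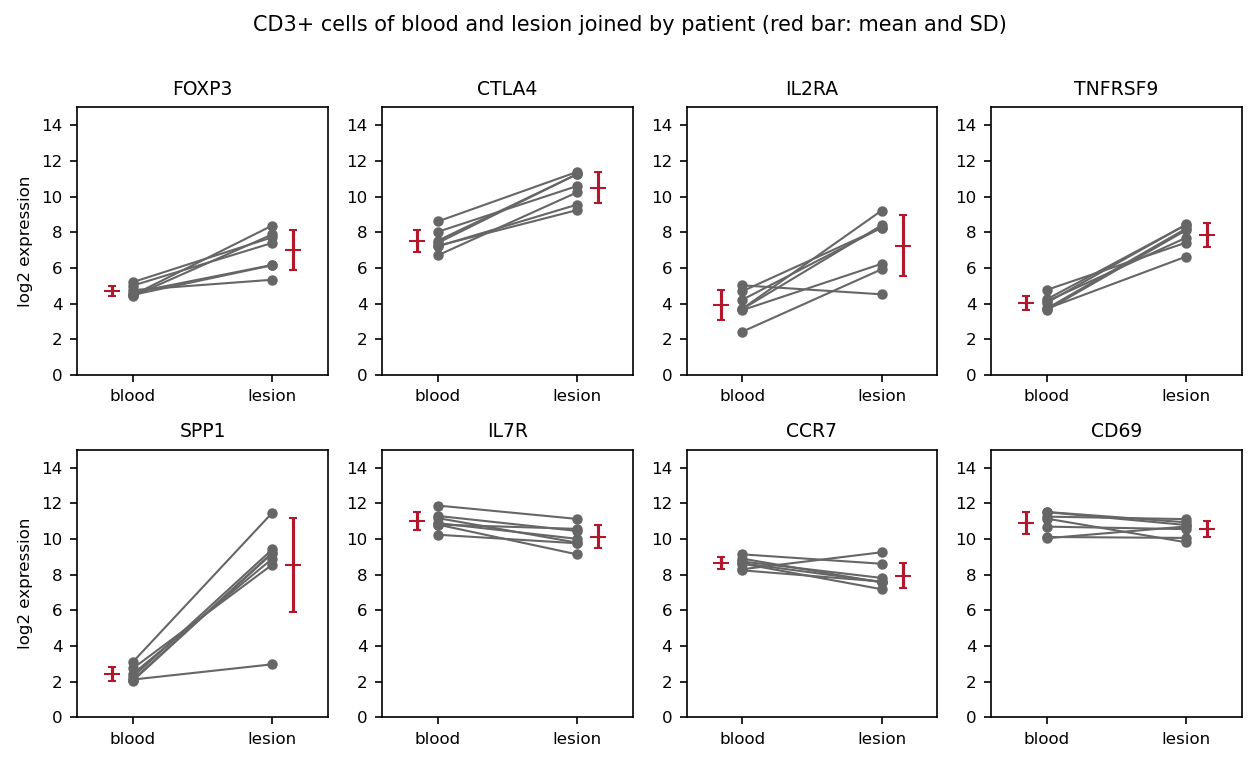
Log2 expression (vertical axis) of 8 genes in CD3+ cells of blood and lesion, with a line for each of the 7 patients and a red bar for the mean and SD of each group. FOXP3, CTLA4, TNFRSF9 and SPP1 are higher in the lesion sample of each pair, while CCR7 and CD69 overlap between the groups.

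In limma's test with the patient as a block and Benjamini-Hochberg adjustment, 3791 of 19740 genes passed, 1795 higher and 1996 lower in lesions, and 1871 differed at least 2-fold (653 higher, 1218 lower). The count depends on single pairs, with 1840, 1993, 2291 and 2387 genes passing without pair 3, 2, 14 or 7. The median difference over all genes was 0.15. SPP1 showed the largest increase (6.13, SE 0.70, adjusted p = 0.000884, higher in 7 of 7 pairs), followed by DUSP4 (5.95), GPNMB (5.73), CD1A (5.61), MMP9 (5.57), BASP1 (5.19), G0S2 (4.92) and MARCKS (4.87). The largest decreases were those of FHIT (-4.01), TRABD2A (-3.70), NOG (-3.56), DACT1 (-3.56), PCSK5 (-3.44), LRRN3 (-3.32), FGFBP2 (-3.20), a gene of cytotoxic lymphocytes, and AMIGO1 (-3.12). CD1A, MMP9, BASP1 and MARCKS lay higher still in lesion CD207+ than in all 12 lesion CD3+ samples, by 5.92, 3.00, 2.59 and 2.03. SPP1 was higher there by 1.94 (limma adjusted p = 0.0725), or by 1.71 (adjusted p = 0.0155) over 10 pairs of the same number, while DUSP4 lay lower, by a difference of -1.48. Among the genes picked in advance, TNFRSF18 (1.25), the granzyme gene GZMK (1.26) and MKI67 (1.78) were higher and the interleukin 7 receptor gene IL7R (-0.89) was lower. The call of GZMK ended without pair 2, 3 or 14 (differences of 1.20 to 1.24) and that of MKI67 without pair 2, 3, 6 or 11 (1.56 to 1.68). The cytokine genes IFNG (0.65, adjusted p = 0.433), TNF (1.14, 0.0946) and IL17A (0.44, 0.0844) did not pass, nor did CCR7 (-0.71, 0.0846), CXCR4 (0.23), CD69 (-0.33) and CCL5 (0.28).

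The regulatory T cell genes TNFRSF9 (3.81), IL1R2 (3.71), ENTPD1 (3.26), BATF (2.67) and TIGIT (2.45) were also higher, and the list passed camera (adjusted p = 1.89e-09; adjusted p = 0.171 with an estimated correlation). Of its 14 higher genes, 11 were lower in lesion CD207+ than in lesion CD3+ samples in an unpaired fit, and 1, TNFRSF9, was higher there (by 1.19). The other 2, IL1R2 (1.09, limma adjusted p = 0.121) and ENTPD1 (0.44, limma adjusted p = 0.522), did not pass. For TNFRSF9, IL1R2 and ENTPD1, RNA of lesional CD207+ cells thus stays open as a source. Naive and central memory genes included NELL2 (-2.40), LEF1 (-1.47) and SATB1 (-1.46); the count was 12 of 12 adjusted over the list alone (camera adjusted p = 4.27e-09, or adjusted p = 0.168 with an estimated correlation). Genes of the T cell receptor complex and signalling were lower for 3 of 13, CD3G (-1.18), LCK (-1.14) and LAT (-0.69), or 5 adjusted over the list alone (camera adjusted p = 0.00103, or adjusted p = 0.397 with an estimated correlation). CD3D was lowest in lesion replicates 9 (8.51) and 14 (8.92), where CD207 was 8.74 and 10.46. The other lesion CD3+ samples, with CD207 above or below 4.00, held CD3D at 9.95 to 10.61. Whether RNA carried over from other cells lowers the share of T cell genes was not tested. T cell activation genes were higher for 8 and lower for 1 of 15, with HLA-DRA (4.36), which lesion CD207+ cells hold at 12.69, and TFRC (1.5; camera adjusted p = 0.0023; adjusted p = 0.271 with an estimated correlation). Chemokines and chemokine receptors of T cells were higher for 10 of 17, or 13 with 1 lower adjusted over the list alone, including CCR1 (3.69), CXCR6 (3.47) and CCR8 (1.61; camera adjusted p = 8.87e-05; adjusted p = 0.116 with an estimated correlation). Tissue residence genes were higher for 5 of 12, with PRDM1 (2.40) and RGS1 (2.06; camera adjusted p = 0.0405; adjusted p = 0.171 with an estimated correlation).

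Helper cell lists differed in how many members passed. Type 2 helper genes were higher for 6 of 9, with HPGDS (3.54), which lesion CD207+ cells hold at 10.88, MAF (1.44) and CCR4 (0.91; camera adjusted p = 0.00186; adjusted p = 0.116 with an estimated correlation). Follicular helper genes were higher for 3 of 10, or 6 adjusted over the list alone, including the B cell attractant CXCL13 (3.29) and ICOS (1.36; camera adjusted p = 0.0117; adjusted p = 0.171 with an estimated correlation). Type 17 helper genes were higher for 4 and lower for 1 of 10, or 6 and 1 adjusted over the list alone, with CCR6 (1.62) and IL23R (0.98) higher and KLRB1 (-1.10) lower (camera adjusted p = 0.0745). Type 1 helper genes had 0 higher and 1 lower, STAT4 (-0.99), of 9, or 1 and 1 adjusted over the list alone (camera adjusted p = 0.249). Cytotoxic effector genes had 2 higher and 1 lower of 16 (camera adjusted p = 0.577; the median was 0.08 and the mean -0.05). Inhibitory receptors were higher for 5, including HAVCR2 (2.26), and lower for 2 of 10, or 6 and 3 adjusted over the list alone (camera adjusted p = 0.101). Cell cycle genes were higher for 8 of 20, or 9 adjusted over the list alone, with AURKA (2.79), TOP2A (1.87) and CDC20 (1.08; camera adjusted p = 0.00499; adjusted p = 0.423 with an estimated correlation). MKI67 lay higher in lesion CD207+ than in all 12 lesion CD3+ samples (7.29 against 5.13, limma adjusted p = 0.00141). TOP2A did not pass there (6.70 against 5.55, limma adjusted p = 0.133). RNA of lesional CD207+ cells thus stays open as a source of a part of this rise. Interferon response genes were higher for 4 of 17, or 5 adjusted over the list alone, with IFI6 (1.90) and ISG15 (1.84; camera adjusted p = 0.00301; adjusted p = 0.439 with an estimated correlation). Of the immediate early and heat shock genes, 1 of 14 was higher, the chaperone HSPA6 (4.41; camera adjusted p = 0.249).

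Langerhans and myeloid cell markers, with LYZ (3.79), CST3 (3.58) and TYROBP (2.66), passed camera (adjusted p = 1.97e-09; adjusted p = 0.171 with an estimated correlation). Mast cell markers were higher for 5 of 7, such as TPSAB1 (0.88; camera adjusted p = 0.00288; adjusted p = 0.116 with an estimated correlation). Eosinophil and granulocyte markers were higher for 5 of 11, or 7 adjusted over the list alone, such as CLC (2.39; camera adjusted p = 0.00601; adjusted p = 0.171 with an estimated correlation). Fibroblast markers were higher for 4 of 11, or 5 adjusted over the list alone, such as COL3A1 (2.87; camera adjusted p = 0.00696; adjusted p = 0.429 with an estimated correlation). Keratinocyte markers were higher for 3 of 16, or 5 adjusted over the list alone, such as DSP (1.39; camera adjusted p = 0.0161; adjusted p = 0.285 with an estimated correlation). B cell markers had 2 higher and 1 lower of 11, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.0745). Plasma cell markers had 4 higher and 2 lower of 9, or 6 and 2 (0.18). Endothelial markers had 1 higher of 10, or 0 in limma's test adjusted over the list alone, where 6 passed unadjusted (0.0928). Erythroid and platelet markers had 1 lower of 8, or 1 higher and 1 lower (0.376). The 3' over 5' log2 ratio was 1.67 ± 0.39 (SD, n = 7) in lesions and 2.06 ± 0.22 (SD, n = 7) in blood (2-sided exact sign-flip permutation p = 0.0156, the smallest 7 pairs allow; adjusted p = 0.0234). With the 3' over 5' ratio as a covariate, which correlated with the group at r = -0.545, 41 genes passed. With the mean of the myeloid markers, which correlated with the group at r = 0.832, 9 passed. Both covariates take up a part of the difference between the groups, so these losses do not show what caused the calls. Over the 2 pairs whose lesion sample had CD207 under 4.00, limma called 0 genes, with 2906 at an unadjusted p under 0.05.

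The last comparison set the 12 lesion CD3+ samples against 4 pools of tonsil CD3+ cells, T cells of a lymphoid organ of other people. Lesion CD3+ cells held less of the genes of follicular helper T cells, which aid B cells in germinal centres. Of 10 measured genes 7 were lower and 0 higher, including CXCL13 at 4.14 ± 1.95 (SD, n = 12) against 9.43 ± 0.21 (SD, n = 4), a difference of -5.29 (SE 0.88), and the cytokine gene IL21 (-4.21, SE 0.23). FOXP3 was higher, at 6.46 ± 1.13 (SD, n = 12) against 4.76 ± 0.27 (SD, n = 4), a difference of 1.70 (SE 0.54). Its call ended in 10 of 16 fits that left out 1 sample. CTLA4 (-0.53, SE 0.41) did not pass. Langerhans and myeloid cell markers were higher for 6 of 16 and lower for 0 in the same samples, or 12 adjusted over the list alone. The B cell genes MS4A1 and POU2AF1 were lower there too, at 2.86 and 4.59 against 6.78 and 10.46 in tonsil. Of 11 B cell markers 3 were lower and 2 higher.

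**Figure D3:**
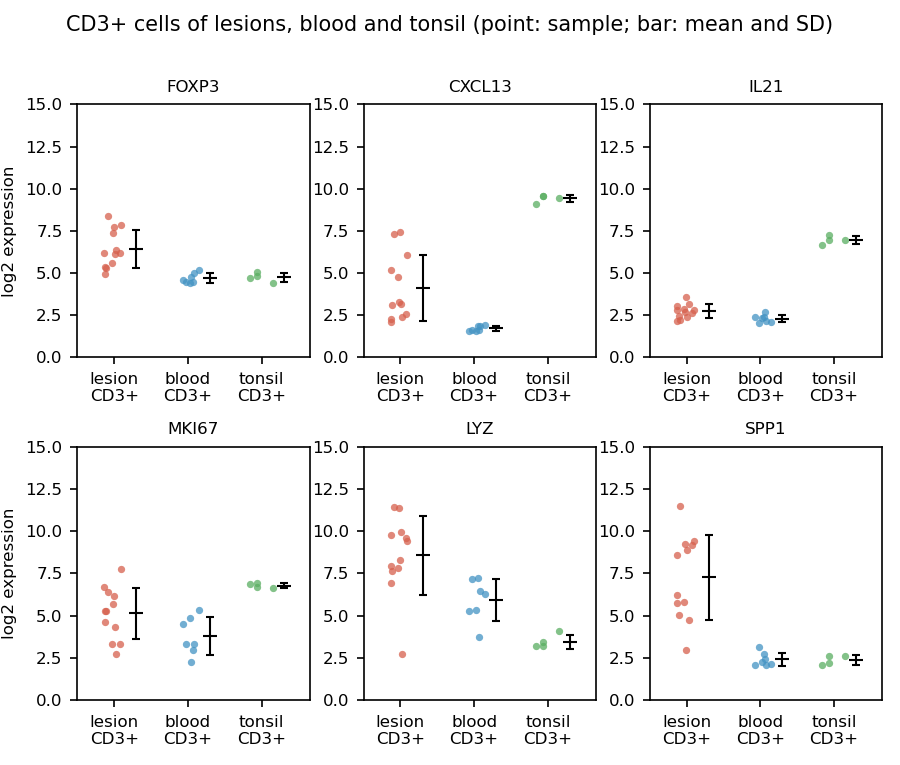
Log2 expression (vertical axis) of 6 genes in CD3+ cells of lesions, blood and tonsil; each point is a sample, a tonsil point is a pool of 5 tonsils, and the bars give the mean and SD. CXCL13 and IL21 lie highest in the tonsil pools, FOXP3 averages 6.46 in lesions against 4.71 in blood and 4.76 in tonsil, and LYZ and SPP1 spread widely among lesion samples.

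In limma's test with Benjamini-Hochberg adjustment 2519 of 19740 genes passed, 1392 higher and 1127 lower in lesions, and 1285 differed at least 2-fold (307 higher, 978 lower). The median difference over all genes was 0.12. The largest increases were those of LYZ (5.11, SE 1.05, adjusted p = 0.00953), the lysozyme gene of myeloid cells, MMP9 (5.04), SPP1 (4.90), CXCL8 (4.30), GPNMB (4.24), G0S2 (4.12), SERPINA1 (3.83) and FCGR2A (3.72). The largest decreases were those of POU2AF1 (-5.87), a coactivator known from B cells, CXCL13, HEY1 (-4.69), CH25H (-4.62), KSR2 (-4.38), TOX2 (-4.37), CHGB (-4.23) and IL21 (adjusted p = 2.01e-09). Of the genes picked in advance TNFRSF18 (1.52) was higher, while IL2RA (1.18, adjusted p = 0.216), MKI67 (-1.66, 0.104), IL7R (-0.59, 0.403) and CCR7 (-0.29, 0.499) did not pass. GZMK (-0.53), IFNG (-0.43), TNF (-0.93), CXCR4 (0.27), CD69 (0.01) and CCL5 (0.42) did not pass either. IL17A (0.18, adjusted p = 0.47) has 2 probe sets, of which 1 was called lower, and the mean of the 2 was lower (-1.92).

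Follicular helper genes, with TOX2, BTLA (-3.24) and MAF (-2.38), numbered 8 lower adjusted over the list alone and passed camera (adjusted p = 7.93e-09), also with the correlation estimated (adjusted p = 0.00191 with an estimated correlation). Genes of the T cell receptor complex and signalling were lower for 6 of 13, such as CD3D (-1.23) and LAT (-1.03), or 8 adjusted over the list alone (camera adjusted p = 7.78e-05, or adjusted p = 0.329 with an estimated correlation). Here too, whether RNA carried over from other cells lowers their share was not tested. Cell cycle genes were lower for 5 of 20, such as TYMS (-2.22) and CCNB2 (-1.97), or 9 adjusted over the list alone (camera adjusted p = 2.45e-05, or adjusted p = 0.329 with an estimated correlation). Inhibitory receptors were lower for 1 of 10, BTLA, or 6 adjusted over the list alone (camera adjusted p = 0.00223, or adjusted p = 0.329 with an estimated correlation). Naive and central memory genes were lower for 1 of 12, ACTN1 (-2.73; camera adjusted p = 0.0153; adjusted p = 0.346 with an estimated correlation). Interferon response genes were higher for 5 of 17, such as IFI44L (3.02), IFI27 (2.03) and IFI44 (1.73), or 10 adjusted over the list alone (camera adjusted p = 0.000372, or adjusted p = 0.405 with an estimated correlation). Regulatory T cell genes were higher for 4 of 16, FOXP3, TNFRSF18 and TNFRSF9 (1.89) among them, and lower for 1, IL10 (-1.31), or 5 and 2 adjusted over the list alone (camera adjusted p = 0.408).

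The other T cell lists did not pass camera. T cell activation genes had 2 higher and 2 lower of 15, with NFATC1 (-2.63) and CD38 (-1.46) the lower (adjusted p = 0.77; the median was 0.09 and camera's direction downward). Chemokines and chemokine receptors of T cells had 2 higher and 1 lower of 17, or 3 and 1 adjusted over the list alone (0.645), and tissue residence genes 1 higher and 2 lower of 12, ITGAE (-1.52) and DUSP6 (-2.06; 0.408). Type 1 helper genes had 1 higher of 9 (0.834; the median was 0.10 and the mean -0.07), type 2 helper genes 1 higher and 1 lower of 9 (0.366), and type 17 helper genes 1 lower of 10 (0.55; the median was 0.14 and the mean -0.20). For cytotoxic effector genes limma called 0 of 16, where 3 passed unadjusted (camera adjusted p = 0.408). Immediate early and heat shock genes had 1 lower of 14, FOS (-1.34; 0.514).

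Langerhans and myeloid cell markers, such as TYROBP (3.29) and FCER1A (3.00), passed camera (adjusted p = 2.45e-05; adjusted p = 0.346 with an estimated correlation). Mast cell markers were higher for 2 of 7, such as TPSAB1 (0.98), or 5 adjusted over the list alone (camera adjusted p = 0.00299, or adjusted p = 0.185 with an estimated correlation). Eosinophil and granulocyte markers were higher for 2 of 11, or 5 adjusted over the list alone (camera adjusted p = 0.0034, or adjusted p = 0.185 with an estimated correlation). Erythroid and platelet markers were higher for 2 of 8, such as PF4 (0.98), or 3 adjusted over the list alone (camera adjusted p = 0.0117, or adjusted p = 0.185 with an estimated correlation). Keratinocyte markers were higher for 3 of 16, such as KRT16 (1.23; camera adjusted p = 0.0176; adjusted p = 0.346 with an estimated correlation). Endothelial markers passed camera (adjusted p = 0.0457; adjusted p = 0.364 with an estimated correlation) although limma called 0 of 10, where 3 passed unadjusted. B cell markers had 2 higher and 3 lower of 11, including MS4A1 (-3.92) and CR2 (-1.81; camera adjusted p = 0.105), and plasma cell markers 2 higher and 1 lower of 9, POU2AF1 (0.658; the median was 0.03 and the mean -0.49). Fibroblast markers had 1 lower of 11, COL6A3 (-3.76), or 6 higher and 1 lower adjusted over the list alone (0.119). The 3' over 5' log2 ratio was 1.82 ± 0.40 (SD, n = 12) in lesions and 2.23 ± 0.33 (SD, n = 4) in tonsil pools (2-sided exact permutation p = 0.0934). The calls rest on each tonsil pool, since 373, 362, 298 and 1077 genes passed without pool 1, 2, 3 or 4. The call of FOXP3 ended without any 1 of these pools and without lesion replicate 3, 4, 6, 7, 9 or 14 (differences of 1.57 to 1.80). Those of SPP1, MMP9, GPNMB, CXCL8, SERPINA1 and TNFRSF18 ended without pool 1, 2 or 3 (1.36 to 5.12). That of FCGR2A ended without any 1 of the 4 pools (3.59 to 3.85). With the 3' over 5' ratio as a covariate (r = -0.436 with the group) 892 genes passed, and with the mean of the myeloid markers (r = 0.624) 812.

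**Figure D4:**
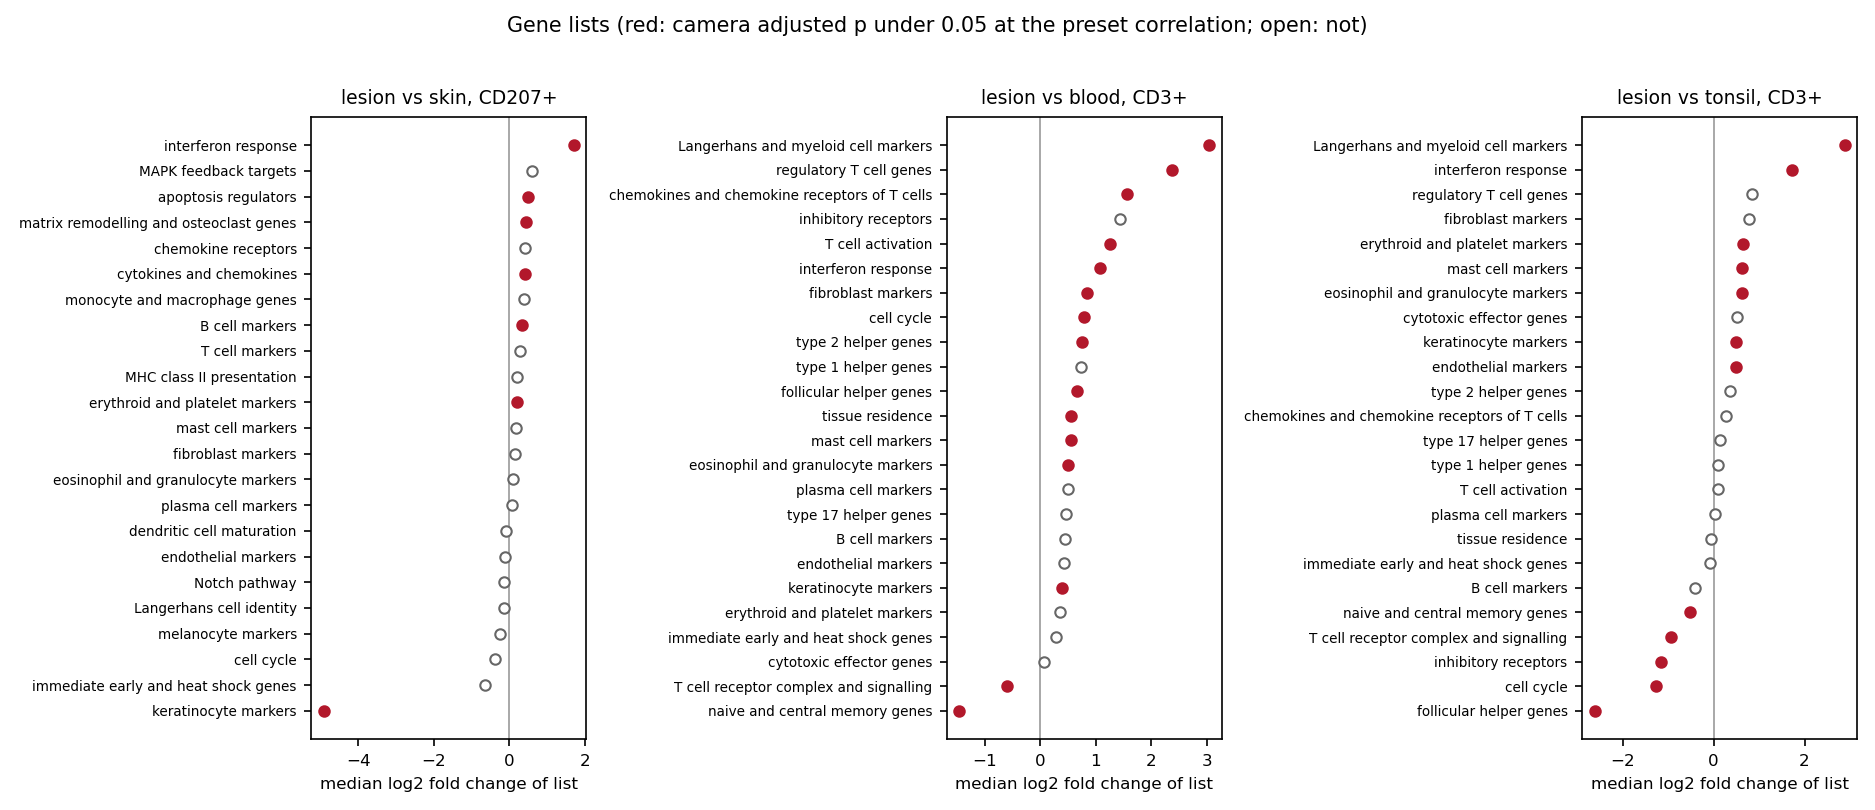
Median log2 difference of each fixed gene list (horizontal axis, lesion minus control) in the 3 comparisons; a point is a list, filled red where camera's adjusted p at the preset correlation is under 0.05 and open where it is not. Keratinocyte markers stand at -4.92 for lesion against skin, Langerhans and myeloid cell markers at 3.04 and 2.88 for lesion CD3+ against blood and tonsil, and follicular helper genes at -2.62 against tonsil.

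The differences of lesion CD3+ cells from blood and from tonsil were set side by side across genes, which are not independent replicates. Both comparisons called 435 genes higher and 458 lower, and 32 genes in opposite directions, where independent lists would share 127, 114 and 243. Among the genes higher in both were SPP1, GPNMB, MMP9, FOXP3 and TNFRSF9, while CXCL13 was higher than in blood and lower than in tonsil. Against tonsil the calls of SPP1, GPNMB and MMP9 ended in 3 of 16 fits that left out 1 sample, and that of FOXP3 in 10. The log2 differences correlated at r = 0.621 (rho = 0.671) with a covariance of 0.310. Unchanged groups simulated with the shared lesion samples gave r = 0.520 and a covariance of 0.0419. The covariance differed by 0.268. With separate lesion samples (7 against blood and 5 against tonsil) r was 0.476 and the covariance 0.260. In both, 165 genes were higher and 254 lower, against 68.0 and 99.5 for independent lists.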

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

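Chosen after the result was seen were the test between cell types and the tests of keratinocyte markers, EPCAM, Langerhans and myeloid genes, SPP1, the set of FOXP3, CTLA4, TIGIT and ICOS, the FOXP3 level, and the levels predicted from CD207 and CD1A.

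The number of calls was set against other splits of the same samples. Of 100 splits of the CD207+ samples 1, the real one, gave as many calls (4797 against 1238 at most in the others). Of the 64 exchanges of lesion and blood within pairs 1, the real one, gave as many (3791 against 23), and of 100 splits of the lesion and tonsil samples 1, the real one (2519 against 358).

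The first pattern is the lower level of keratinocyte genes in lesion CD207+ cells, for which RNA of keratinocytes carried over in the skin sorts, although these selected for CD207, is a candidate source. Across the 12 skin samples, where PERP averaged 11.54 and KRT1 11.50, the markers moved together with a median pairwise r of 0.597, at percentile 100 of 1000 gene sets matched on level. Those sets were random genes matched on level alone. The test therefore cannot tell carried-over RNA from markers regulated together within the sorted cells. The 2677 other genes called lower had a median rho of only 0.021 with the keratinocyte mean (-0.018 over 11 samples, without skin replicate 1). That was 0.203 above the -0.182 of matched genes without a call, or 0.155 above them over 11 samples. The interval for 0.203, 0.175 to 0.231, comes from resampling genes, which are not independent. It leaves out the spread between samples. Of the genes called lower 19.1% had a rho over 0.5 against 3.06% of the matched genes. Both differences, 0.203 and 0.155, exceeded the limit set beforehand as the mark of carried-over RNA. Carried-over RNA thus stays a candidate source for a part of the genes called lower. Compared with matched genes, the typical gene called lower followed the markers more closely, though its own rho was only 0.021. EPCAM did not follow them, with a rho of -0.441 (permutation p = 0.156, interval -0.813 to 0.201, n = 12), or -0.355 without skin replicate 1 (permutation p = 0.29, n = 11). Its r was -0.344 (permutation p = 0.272, or r = -0.322 without the 2 farthest samples). The cell junction gene CDH1 did not follow them either (rho = -0.045, n = 11). For EPCAM the lack of a relation thus gives no sign of carried-over RNA but cannot exclude it. A difference between lesion and skin CD207+ cells themselves stays open for EPCAM and the other genes, since group and keratinocyte mean correlate at -0.980.

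A further pattern is the higher level of Langerhans and myeloid genes in lesion CD3+ samples, which may come in part from RNA of lesional CD207+ cells carried over despite the CD3 sort. Over the 12 lesion samples the other myeloid markers followed the mean of CD207 and CD1A (r = 0.920, permutation p = 0.00024, adjusted p = 0.0012 over 5 relations, rho = 0.895, p = 0.00027, r = 0.922 without the 2 farthest samples), as did SPP1 (r = 0.671, p = 0.0192, adjusted p = 0.0479, rho = 0.699, p = 0.0137, r = 0.632), but the samples part into 6 at 2.19 to 3.94 and 6 at 6.19 to 10.62, and within 6 samples neither passed, with r = 0.731 for the markers and 0.607 for SPP1 in the lower part (exact permutation p = 0.0764 and 0.197, rho = 0.83 and 0.49, r = 0.689 and 0.295 without 2) and r = 0.294 and -0.285 in the higher part (p = 0.596 and 0.561, rho = 0.314 and -0.257, r = -0.070 and 0.786 without 2). Against that RNA as the only source, SPP1 lay 2.58 above the level predicted from CD207 and CD1A (exact sign-flip p = 0.000977, n = 12). With same-numbered samples it lay 2.44 above (p = 0.0137, n = 10). In lesion replicates 4, 5 and 7, CD207 (2.60 to 2.78) and CD1A (1.66 to 2.05) lay within the range of blood and tonsil. The prediction there rests on background levels. The excess of the other markers was smaller (0.57, p = 0.000488, or 0.47 with same-numbered samples, p = 0.0137). It lay above 0 in 12 of 12 samples, and whether the prediction itself falls short was not tested. That RNA as the only source stays open for them. FOXP3, CTLA4, TIGIT and ICOS are not explained by that RNA, since 4 of these 4 genes were lower in lesion CD207+ than in lesion CD3+ samples in limma's test (by -1.58, -6.66, -3.84 and -6.33, or -1.72, -6.67, -4.24 and -6.35 over 10 pairs of the same number), whereas FOXP3 (r = 0.331, permutation p = 0.29, adjusted p = 0.483, rho = 0.273, p = 0.393, r = 0.310 without 2), the cell cycle mean (r = 0.240, p = 0.448, adjusted p = 0.521, rho = 0.287, p = 0.368, r = 0.232) and CTLA4 (r = 0.202, p = 0.521, adjusted p = 0.521, rho = 0.266, p = 0.401, r = 0.369) left open whether they vary with it. Other myeloid cells of lesions and SPP1 made by T cells stay open, as untested.

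The remaining pattern is a small shift by level in lesion CD3+ samples, upward by a median of 0.21 against blood and 0.23 against tonsil in the dimmest of 5 equal bins of genes and downward in the 2 brightest bins (-0.26 and -0.31 against blood, -0.40 and -0.39 against tonsil). A candidate explanation is a narrower range of values on these arrays, whose SD across genes was 2.12 ± 0.10 (SD, n = 12) against 2.28 in blood and 2.24 in tonsil. Quantile normalization, which removes such a range whatever its origin, left 35% of the dimmest bin's shift against blood and 49.7% of that against tonsil, and 25.8% and 38.3% (blood) and 47.8% and 60.9% (tonsil) of those of the brightest bins. In the bin after the dimmest, where the shifts were larger (0.32 and 0.37), it left 64.6% and 76.2%, and in the middle bin (0.28 and 0.29) 106% and 115%, so the range accounts in part for the shifts of the dimmest and brightest bins and not for that of the middle bin. Whether the rest comes from cells or amplification was not tested.

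Of 80 sets of samples tested for a sample far from the others 5 had one, where chance gives about 1 in 20 (5.2% of simulated groups of 4 and 5.3% of groups of 7 normal values). The sets are not independent, since they share samples and genes. The mean of interferon response genes was 8.20 in blood replicate 9, against 5.43 to 6.41 in the other blood samples, and 6.15 in tonsil pool 2, against 5.49 to 5.53 in the other pools. Tonsil pool 2 also had a mean of 9.09 for the T cell receptor complex and signalling genes, against 9.43 to 9.49. The mean of endothelial markers was 4.06 in blood replicate 14 (others 3.65 to 3.82), and that of eosinophil and granulocyte markers 2.51 in blood replicate 3 (others 2.64 to 2.72).

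At camera's preset correlation, cell cycle genes differed between the cell types in how lesion and control compare, with tonsil as the control of CD3+ cells. They were the only 1 of 7 items tested that passed. Their median difference was -0.38 for CD207+ cells (lesion minus skin) and -1.27 for CD3+ cells (lesion minus tonsil), and the median difference of differences per gene was 0.70 (camera adjusted p = 0.009; adjusted p = 0.772 with an estimated correlation). MKI67 alone did not pass (1.16, limma adjusted p = 0.288). Against blood the list went the other way in CD3+ cells (median 0.78, camera adjusted p = 0.00499; adjusted p = 0.423 with an estimated correlation, and a median of -0.040 with RNA quality as a covariate). The difference between cell types was not tested with blood as the control.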

How the results depend on the processing

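Leaving out the samples in doubt was chosen after the data were seen. The other settings were planned, and where no reason is given for a change the cause was not tested. Offsets before the logarithm were not run, as the values are already log2. Without raw scans the signal over background is unknown, so what a low level limits could not be measured. Over all settings and samples left out, named genes kept their side of the threshold without a turn of a called direction in 3814 of 4011 values against skin, 1643 of 2098 against blood and 2759 of 3203 against tonsil, although 23, 12 and 20 of these changed sign without a call. Only 17 of 112, 12 of 112 and 28 of 111 named genes kept their side in this sense in every planned setting other than leaving out single samples or pairs. Genes that stayed without a call count among them. The marker means used as covariates, which follow the group (r = -0.980 against skin and 0.832 against blood), kept 1 and 7 of the main calls. At most 1 of the 17 and 7 of the 12 can therefore be called genes. Calls ended in 128, 399 and 317 values and were gained in 44, 52 and 126, and the called direction turned in 25, 4 and 1. For gene lists 793 of 873, 441 of 502 and 702 of 744 values kept their side, of which 24, 9 and 19 changed camera's direction without a call, 35, 41 and 32 ended, 41, 17 and 9 were gained, and 4, 3 and 1 turned.

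Leaving out 1 sample in turn gave 4282 to 4952 calls against skin (1831 to 2274 higher, 2451 to 2827 lower) and 298 to 2811 against tonsil (105 to 1549 higher, 193 to 1276 lower), with 373, 362, 298 and 1077 without pools 1 to 4, where fewer pools remain. Leaving out 1 pair gave 1840 to 3367 against blood (734 to 1671 higher, 1106 to 1734 lower), with 1993, 1840, 2387 and 2291 without pairs 2, 3, 7 and 14.

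Testing every probe set, of which there are more, called 9326 probe sets against skin (4130 higher, 5196 lower), 7094 against blood (2809 and 4285) and 1900 lower ones against tonsil. Requiring 2-fold left 1646 (504 and 1142), 1871 (653 and 1218) and 1285 (307 higher). Quantile normalization left 2379 (1151 and 1228) against blood and 1295 (685 and 610) against tonsil, and 48.4% and 52.9% of calls were then higher, against 47.3% and 55.3%. Median centring left 37.4% and 47.5% higher. Against skin the share higher went from 43.9% to 50.9% after quantile normalization (2742 higher, 2645 lower) and 49.9% after median centring (2549 and 2555), so the excess of lower calls depends on the normalization. Leaving out dim genes gave 1018 higher against blood. Array weights gave 7182 against tonsil (4059 and 3123). The mean of probe sets turned IL17A against tonsil to -1.92.

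RNA quality as a covariate left 2778 calls against skin (888 higher), 41 against blood (14 and 27) and 892 against tonsil (366 and 526). It turned camera's direction for the fibroblast list against skin, whose median went from 0.14 to 0.39 and which then passed (adjusted p = 0.0468), and for the cell cycle list against blood (0.78 to -0.040). The myeloid mean as a covariate left 9 against blood (7 and 2) and 812 against tonsil (318 and 494). Against blood it turned MARCKS to -0.25, HPGDS to -0.011, AHR to -0.61, FCGR3B to -0.59 and the camera direction of the Langerhans and myeloid list, whose median was 0.28. Against tonsil it turned that list's direction too (median 0.11). This covariate correlates with the group at 0.832 and 0.624, and RNA quality at -0.545 and -0.436.

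The keratinocyte mean as a covariate, with r = -0.980 to the group and a median SE of 0.811 against 0.164, left 1 call against skin, 0 higher and 1 lower in limma, where 2450 passed unadjusted, 688 of them higher. It turned ITGA2B to -0.69, CNIH3 to -1.87, AFF3 to -0.59, CCL5 to -0.015, MMP9 to -0.50, CD2 to -0.0013, CTSH to -0.34, TGFB1 to -1.40, ETV5 to -0.52 and BAX to -0.61. It turned SPRR1B to 1.63, CDH1 to 0.22, CD36 to 0.65, NOTCH3 to 0.24, CCL22 to 0.069, IDO1 to 1.63, HES1 to 2.15, JAG1 to 4.35, EPHA4 to 0.26, TYRP1 to 0.25, PMEL to 1.48, MLANA to 0.99, SDC1 to 0.060, DCN to 4.42 and KIT to 2.45. It turned camera's direction for Notch pathway (median -0.14 to 0.86), melanocyte markers (-0.25 to 0.99) and fibroblast markers (0.14 to 3.42), all of which then passed camera upward (adjusted p = 0.0139, 0.025 and 0.00126).

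Samples in doubt left out gave 4731 calls against skin and 2663 against tonsil. The rule used CD207 alone, so lesion CD3+ replicates 8 and 11, with CD1A at 4.75 and 5.82, stayed in. Against blood 2 pairs remained, and limma called 0 genes, 0 higher and 0 lower, with 2906 unadjusted. Camera's direction for the cytotoxic effector list then turned (median 0.08 to 0.89) and the list passed (adjusted p = 0.0179). With the 7 or the 5 lesion samples that have or lack a blood sample, 842 and 748 genes were higher than in tonsil. The agreement between the comparisons with blood and tonsil was r = 0.476 with separate lesion samples and 0.644 over genes called in either.

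The replicate number as a block gave 3635 calls against skin and 231 against tonsil (75 and 156), where only 4 lesion samples share a number with a pool. The numbers pair no samples there, as same-numbered samples correlated at medians of -0.0099 and -0.032, 0 of 10 and 0 of 4 over 0.1, and 1 sample of each comparison correlated best with its own number. Without the replicate block against blood 4602 genes were called, and with a random patient block over all lesion samples 7277 (4764 higher).

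Camera passed 7 of 23, 15 of 24 and 12 of 24 lists. With an estimated correlation 1, 0 and 1 passed camera, and 3, 5 and 4 had an unadjusted p under 0.05. Fry passed 14, 15 and 12 of all lists, 7, 11 and 11 of them among those past camera.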

Other observations

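Chosen after values were seen were the comparison of the control groups, the comparison of the lesion groups with its block by number, and the genes named in the last paragraph.

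The blood and tonsil controls of CD3+ cells differed from each other, which places the lesion cells between them for several genes. Follicular helper genes were lower in blood than in tonsil, with a median of -3.16 (camera adjusted p = 3.91e-20; adjusted p = 7.65e-05 with an estimated correlation). CXCL13 was 1.72 ± 0.16 (SD, n = 7) in blood, 4.14 ± 1.95 (SD, n = 12) in lesions and 9.43 ± 0.21 (SD, n = 4) in tonsil. Cell cycle genes were lower in blood too, with a median of -1.86 (adjusted p = 3.21e-17; adjusted p = 0.01 with an estimated correlation), MKI67 among them. Regulatory T cell genes were lower in blood (median -1.54, adjusted p = 2.11e-08; adjusted p = 0.000827 with an estimated correlation), as were inhibitory receptors (-2.21, adjusted p = 8.98e-09; adjusted p = 0.0101 with an estimated correlation), including CTLA4 (-3.24) and TIGIT (-3.74). FOXP3 did not follow, at 4.71 ± 0.30 (SD, n = 7) in blood and 4.76 ± 0.27 (SD, n = 4) in tonsil (limma adjusted p = 0.914), against 6.46 ± 1.13 (SD, n = 12) in lesions. B cell genes differed along with these lists, MS4A1 at 2.34 ± 0.39 (SD, n = 7) in blood and 6.78 ± 0.90 (SD, n = 4) in tonsil and POU2AF1 at 4.31 ± 0.99 (SD, n = 7) and 10.46 ± 0.11 (SD, n = 4). Blood samples come from patients and tonsils from other people, so tissue and donor differ together.

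Of the 1795 genes higher in lesion than in blood CD3+ cells, 498 (27.7%) were higher in lesion CD207+ than in lesion CD3+ cells and 302 (16.8%) lower, where 15.8% and 12.8% of all genes were. Of the 1392 genes higher than in tonsil, 142 (10.2%) were higher in lesion CD207+ cells and 206 (14.8%) lower. These counts come from an unpaired fit of 13 against 12 samples. Both sets of genes were picked for high values in lesion CD3+ samples that the counts use again. That favours calls of lower in lesion CD207+ cells, and no simulation of unchanged groups was set beside them. Same-numbered samples of the lesion groups, which the design text does not pair, deviated from their group means together (median r = 0.163 against -0.025 for other numbers, 8 of 10 over 0.1). With the number as a block over these 10 pairs, 479 (26.7%) of the genes higher than in blood were higher in lesion CD207+ cells and 313 (17.4%) lower, and 137 (9.84%) and 165 (11.9%) of those higher than in tonsil, where 16% and 11.1% of all genes were. Of the 14 regulatory T cell genes higher than in blood, 10 were then lower and 1 higher in lesion CD207+ cells.

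Other genes differed between lesion and skin CD207+ cells outside the rule for named genes. CDKN2A, an inhibitor of the cell cycle, was 6.91 ± 0.76 (SD, n = 13) in lesions and 3.23 ± 0.48 (SD, n = 12) in skin, a difference of 3.69 (SE 0.25, limma adjusted p = 3.16e-12). HIF1A, a transcription factor of the response to low oxygen, was higher by 2.29 (SE 0.16), and the cytokine receptor kinase JAK3 by 2.81 (SE 0.33). PDGFA, a growth factor that keratinocytes also make, was lower (-4.21, SE 0.34).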
